A study of Mus musculus with 2 samples.

How the data were processed

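Small intestine of 1 Tg (Mdm2+/- Cag-CreERTg) and 1 FMTg mouse (Mdm2FM/- Cag-CreERTg) was profiled with the 10x Genomics Chromium 3' single-cell protocol, which counts unique molecular identifiers (UMIs) near the 3' end of each transcript. The deposited values are raw UMI counts per gene and cell barcode. The tools CASAVA 1.8.1 and Cell Ranger 3.0 and the genome build mm10 are named in the submitters' processing notes, and the annotation release is not given in the sources used here. The files list 31053 gene symbols in the same order, of which 30532 matched 1 gene of GENCODE vM21, from which positions were taken.

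Each group has 1 library, so no test, p-value, standard error or count of genes past a test was computed. Groups followed the sample labels. Sums of UMIs have exact Poisson intervals, ratios of sums exact conditional binomial intervals and shares of cells exact Clopper-Pearson binomial intervals, all at 95% and covering counting error only. The interval of a difference of shares was joined from the exact intervals of both shares by Newcombe's method. List medians have intervals from 2000 redraws of the counts.

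Barcodes with at least 500 UMIs, at least 300 genes and at most 25% mitochondrial UMIs were kept. The UMI and gene minimums removed 257 Tg and 210 FMTg barcodes, and the mitochondrial limit 2946 and 3353. Doublets were scored per library with the scrublet method of scanpy 1.11.5, and the highest-scoring cells were removed at an expected rate of 0.800% per 1000 barcodes, 154 of 3067 Tg and 144 of 2819 FMTg cells. The automatic threshold marked 24 and 27. The doublet rule was altered after the data had been seen: the automatic threshold was tried first, then that threshold with the expected rate as a fallback, which treated the libraries unequally, then the expected rate from filtered cells and last from barcodes in the files.

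Retained cells of both libraries were clustered together on 2000 variable genes, 30 principal components and 20 exact nearest neighbours with leidenalg 0.10.2 at resolution 1, giving 23 clusters. Variable genes excluded 7 lists: p53 targets, both cell cycle lists, stress, interferon, ribosomal proteins and mitochondrially encoded genes. Clusters were named from markers of 22 cell types, with at least 3 detected markers. Further naming rules were added after the clusters had been seen and went through several forms. A crypt name first needed Epcam in at least 50% of cells, and later more Epcam than Ptprc CPM. A cluster stays unnamed where another class has more markers among its 10 leading genes, and a rule on 2 leading genes of another class was worded so that the cluster led by Ccl9 keeps its macrophage name. Clusters 12 and 18 were left unnamed.

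UMIs were summed per library and cell class and scaled to the total UMIs of the class in that library (CPM). Medians were taken over list members with at least 20 UMIs over both libraries. The 25 gene lists, the markers, the groups, the rule for named genes and 17 alternatives were chosen before the data were examined. The rule takes the 10 highest and 10 lowest log2 CPM ratios in crypt progenitors, enterocytes and all cells among genes with at least 100 UMIs, with a library at 0 set to 3 counts. Xist, Tsix, Y-linked, immunoglobulin and T-cell receptor segments, mitochondrially encoded and ribosomal protein genes were left out of that ranking. Of the genes so ranked, 1 is not reported here. Mdm2, Trp53 and Cdkn1a are always named, and from each list up to 4 members with the most UMIs and up to 4 with the largest absolute ratio among those with at least 50 UMIs. Each list median was placed among 10000 random lists of equal size matched on mean expression. For the cycling share, cells were thinned without replacement to 2000 UMIs.

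The alternatives covered the mitochondrial limit, the UMI minimum, doublets, 3 other scalings (TMM of edgeR 4.0.16, size factors of DESeq2 1.42.0, and totals without mitochondrial and abundant genes), the gene minimum, equal weight per cell, the clustering, the variable genes and the thinning. After the data had been seen 5 more were added: a 50% mitochondrial limit, the automatic doublet threshold, naming by marker score alone, and the enterocyte-like class without the cluster mostly of FMTg or without its shallow cluster. Some tests of explanations were also revised after their results had been seen. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3, with seed 1.

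The ratio and list calculations were tested on simulated counts with 200 altered genes, 100 at each fold size. In the crypt simulation of 7679 genes, a true median log2 ratio of 0.92 was found as 0.89 for 2-fold genes, and 1.92 as 1.96 for 4-fold genes. In the enterocyte simulation of 10540 genes, 0.95 was found as 0.96 and 1.95 as 1.97. In the all-cell simulation of 14110 genes, 0.96 was found as 0.95 and 1.96 as 1.96. Intervals held the true ratio for 96.6%, 95.7% and 95.5% of genes. The simulated class sums were drawn from pooled proportions without variation between cells. This coverage therefore concerns counting error only and does not extend to genes whose UMIs lie mostly in single cells.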

Results

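The small intestine of 1 Tg mouse (Mdm2+/- Cag-CreERTg, which retains Mdm2 by the labels) and 1 FMTg mouse (Mdm2FM/- Cag-CreERTg, in which the labels place acute p53 activation through loss of Mdm2) was profiled cell by cell. Both were C57BL/6j mice aged 60 days, and the tissue was taken 24 hours after 1 tamoxifen injection of 6 mg per 40 g of body weight. Tamoxifen switches on the CreER recombinase, and Mdm2 encodes the ubiquitin ligase that holds the transcription factor p53 in check. The question is which genes and cell types of the intestine differ between these genotypes. With 1 library per group, no difference here has a replicate check, and every interval is at 95% and covers counting error only.

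The Tg library held 6270 barcodes with 54013005 unique molecular identifiers (UMIs), a median of 5509 per barcode. The FMTg library held 6382 barcodes with 49805718 UMIs, a median of 5109. After the filters 2913 Tg and 2675 FMTg cells were kept, with median depths of 4938 and 4710 UMIs and median mitochondrial shares of 11.7% and 14.8%. The limit on mitochondrial UMIs removed 47.0% of Tg and 52.5% of FMTg barcodes. Among barcodes with more epithelial than immune marker UMIs it removed 74.1% in Tg and 77.5% in FMTg, against 17.4% and 26.0% on the immune side, so it can set the shares of cell types. Xist had 2 UMIs in Tg and 2 in FMTg, and Y-linked genes had 4185 and 3831.

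Enterocyte-like cells, the absorptive cells of the villus, carried more RNA of p53 target genes in the FMTg library. Mdm2 itself had 1492 UMIs in Tg (exact Poisson interval 1417 to 1570) and 2143 in FMTg (2053 to 2236), a log2 ratio of UMI counts scaled to the class total (CPM) of 0.93 (0.84 to 1.03). Cdkn1a, which encodes the cell cycle inhibitor p21, was higher at 0.77 (0.72 to 0.81), and Ccng1, the cyclin G1 gene, at 0.89. The median over 38 measured p53 targets was 0.64 (0.54 to 0.70), with 20 genes at least 1.5-fold higher and 1 at least 1.5-fold lower. That median lay at percentile 100 among 10000 random lists matched on expression, as a description of these libraries.

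The Mdm2 value does not check the genotype, because the 3' tag need not lie in the deleted part and Mdm2 is itself a p53 target. In mm10, Mdm2 lies on chromosome 10 from 117688875 to 117710758, Trp53, the p53 gene, on chromosome 11 from 69580359 to 69591873, and Cdkn1a on chromosome 17 from 29090976 to 29100727. Trp53 had 149 and 109 UMIs in enterocyte-like cells, a log2 ratio of -0.042 (-0.41 to 0.32). Eda2r, a receptor of the tumour necrosis factor receptor family, was higher at 2.18 (1.75 to 2.64). Pidd1, a death domain gene, was higher at 1.75 (0.85 to 2.72), the stress gene Sesn2 at 1.36 and Psrc1 at 1.33. Bax, the pore-forming apoptosis gene, was higher at 0.38 and Rps27l at 0.41.

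The enterocyte-like class comprised 579 Tg and 508 FMTg cells with median depths of 24020 and 17952 UMIs. Clusters 6, 4 and 9 held 30.7%, 29.2% and 21.2% of its Tg cells, while clusters 5 and 4 held 47.0% and 20.7% of its FMTg cells. Cluster 5, with 22 Tg and 239 FMTg cells, is mostly of 1 library and may be that library, not a cell type, and cluster 6 had a median depth of 1465 UMIs. Inside clusters 4, 6 and 9 the p53 list medians were 0.60, 0.31 and 0.72. Cdkn1a had a UMI in 85.0% of Tg and 94.9% of FMTg enterocyte-like cells, against 14.4% and 13.2% of B-like cells at median depths of 3354 and 3206 UMIs.

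Interferon response genes were also higher in FMTg enterocyte-like cells. Their median was 1.01 (0.89 to 1.12), with 17 of 24 at least 1.5-fold higher and 0 lower. Ifit1bl1 was higher at 1.85, Ifit1 at 1.46, Isg15 at 1.26 and Irf7, a regulator of interferon genes, at 1.13. The chemokine gene Cxcl10 was higher at 3.98. The antiviral gene Rsad2, at 3.84, is also among the leading genes of cluster 5, though its list was left out of the clustering. The list median was 0.55 in cluster 4, 0.087 in cluster 9 and -0.88 in cluster 6, and at a 10% mitochondrial limit it turned to -0.34.

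Secreted antimicrobial genes were lower in FMTg enterocyte-like cells, with a median of -0.64 (-0.98 to -0.63) and 6 of 12 at least 1.5-fold lower. Over 19 alternatives this median ran from -1.30 to -0.19, and 5 values moved beyond the counting interval. Reg3b, a C-type lectin, had 1078472 UMIs in Tg and 390557 in FMTg, a log2 ratio of -1.06. Reg3g was lower at -1.34, while Nos2, the inducible nitric oxide synthase, was higher at 3.67 from 7 and 67 UMIs. Reg3b RNA was also found in T-like or NK-like cells, at 1855 CPM in Tg and 693 in FMTg, and in B-like cells, at 2509 and 871 CPM. Of the lipid absorption genes, with a median of 0.12, Apoa4 was higher at 1.43 and Apoa1 at 0.81, and Fabp2 was lower at -0.67. In the brush border list, with a median of 0.069, Sis, the sucrase-isomaltase gene, was lower at -1.30 and the glucose transporter gene Slc2a2 at -1.31. These single-gene ratios were not recomputed without cluster 5, which held 3.80% of Tg and 47.0% of FMTg enterocyte-like cells.

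Nuclear genes of oxidative phosphorylation were lower, with a median of -0.46 (-0.47 to -0.43) and 22 of 86 at least 1.5-fold lower, but the median was -0.11 without cluster 5 and 0.20 at a 10% mitochondrial limit. Glycolysis genes had a median of -0.37, with Gapdh at -0.56 and Pgam1 at -1.27. Cytosolic ribosomal protein genes had a median of 0.34, with 16 of 79 at least 1.5-fold higher, but -0.12 at a 50% limit. Mitochondrially encoded genes had a median of 0.14. NF-kB and inflammatory genes had a median of 0.88, with Cxcl16 higher at 1.68 and Ccl20 lower at -3.65. The Wnt target median of 0.84 over 9 genes was -0.083 when genes needed 100 UMIs.

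Among the other lists in enterocyte-like cells, anti-apoptotic genes had a median of 0.41, with Bcl2l1 at 0.97, and pro-apoptotic genes outside the p53 list had 0.22, with Bok at 1.30 and the caspase gene Casp6 at -1.07. MHC class II genes had 0.42, regeneration genes 0.42 and ribosome biogenesis genes 0.33, the last -0.0058 at a 50% limit. The regeneration median ran from -0.095 to 0.70 over 18 alternatives. The antioxidant list had -0.24, with Prdx1 at -1.16. The immediate early and dissociation stress list had 0.14, but -0.24 without cluster 5 and -0.77 at a 10% limit, and its heat shock genes Hspa1a and Hspa1b were lower at -4.08 and -3.16. Unfolded protein genes had 0.093, S phase genes -0.067, G2 and M phase genes 0.20, stem cell genes 0.31, proximal genes 0.039 and distal genes 0.021. The brush border, proximal and distal medians were below 0 with TMM scaling, at -0.029, -0.059 and -0.077. At a 10% limit, with 55 and 9 cells, 7 of 16 list medians moved by over 1.5-fold and 8 had the other sign, among them lipid absorption at -0.73, brush border at -0.81, proximal at -0.90 and distal genes at -0.19, the last also at -0.28 at a 50% limit. Haemoglobin genes, which belong to red blood cells and have close copies, had 4.98 in enterocyte-like cells, or 1.57 with no mitochondrial limit, and 5.94 in B-like cells.

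Among the genes with the highest ratios in enterocyte-like cells, Nt5e, an ecto-nucleotidase gene, had 93 and 2144 UMIs (4.94) and Cldn4, a tight junction gene, 54 and 891 (4.45). Without cluster 5 these ratios were 1.44 and 1.06. The hexokinase gene Hk2 was at 4.15 and the long non-coding gene Gm42047 at 4.70. Clu was at 5.37 with UMIs in 9 FMTg cells, Spp1 at 4.15 in 3, Tph1 at 4.51 in 11 and Apoe at 4.04 in 14. With no mitochondrial limit Tph1 was at 0.90 and Apoe at 0.87. Hbb-bs and Hba-a1, at 5.20 and 4.75, have close copies and are uncertain. Their FMTg UMIs, 609 and 183, lay in 19 and 12 cells, against 22 and 9 UMIs in 22 and 9 Tg cells. With no limit the ratios of Hbb-bs and Hba-a1 were 1.34 and 1.63. Of the named enterocyte genes with UMIs in both libraries, 18 of 22 moved by over 1.5-fold with no limit, 17 of 22 with equal weight per cell, 16 of 22 at a 50% limit and 11 of 21 without cluster 5.

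Among the genes with the lowest ratios, the hormone gene Sst had 329 and 1 UMIs, at -7.95 (-13.26 to -5.47), but was at -1.64 with no mitochondrial limit. Gm35082, a long non-coding gene, had 115 and 0 UMIs. It was 28.9-fold lower with FMTg set to 3 counts, with an upper interval end of -4.53 in log2. At a 10% limit it had 4 and 0 UMIs in 55 and 9 cells, too few to give a direction. The chemokine gene Ccl6 was at -4.01, and at -1.23 at a 50% limit. The pancreatic enzyme genes Try5, at -6.71 (-12.02 to -4.21), Cela3b, at -6.32 (-8.60 to -4.76), and Cela2a, at -5.75 (-8.04 to -4.19), have close copies and are uncertain, as are Prss2, Ctrb1 and Try4, at -5.44, -5.28 and -5.23. Their Tg UMIs came from 3 to 9 cells. Their ratios with no mitochondrial limit lay between 0.25 and 2.002, on 3 to 30 Tg UMIs each, and each counting interval included 0. Single Tg cells held 610 of 618 Ctrb1 and 343 of 348 Try4 UMIs. Prss2, Ctrb1 and Try4 turned direction in 6 of 14, 8 of 16 and 7 of 16 alternatives, as to 0.41, 0.83 and 0.90 with doublets kept, where 4 to 9 Tg UMIs were left and the intervals included 0.

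**Figure D1:**
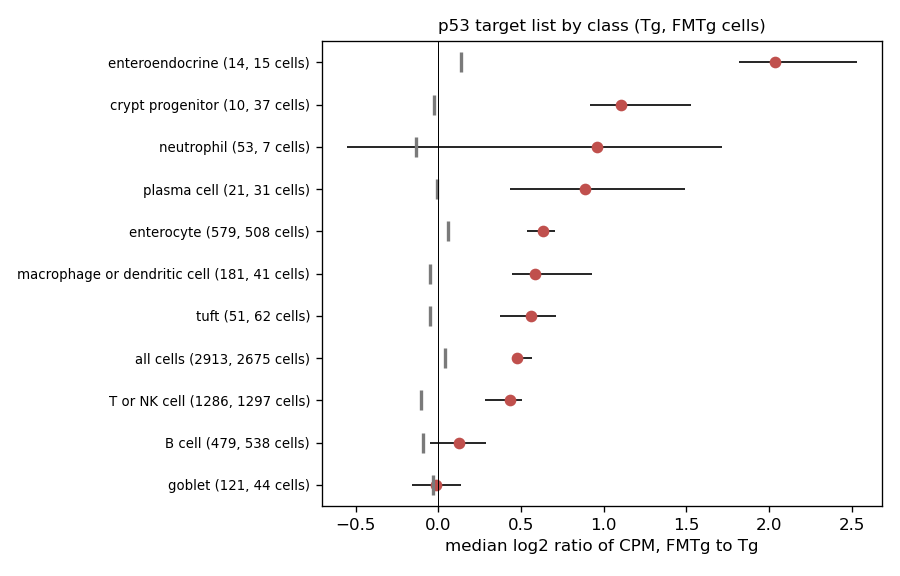
Median log2 ratio of CPM (FMTg to Tg) over the p53-activated targets in each cell class. Points are list medians, lines are 95% counting intervals and grey ticks are the medians of matched random lists; the median was 0.64 in enterocyte-like and -0.015 in goblet-like cells.

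Crypt-progenitor-like cells, the dividing cells at the base of the epithelium, also had more p53 target RNA in FMTg, but rest on 10 Tg and 37 FMTg cells of cluster 19, with median depths of 38548 and 50822 UMIs. Mdm2 had 11 UMIs in Tg (5.49 to 19.7) and 191 in FMTg (165 to 220), a log2 ratio of 1.95 (1.08 to 2.98). Trp53 had 45 and 201 UMIs (-0.010) and Cdkn1a 18 and 391, at 2.27 (1.59 to 3.04). The median over 33 measured p53 targets was 1.10 (0.92 to 1.53), with 24 at least 1.5-fold higher and 0 lower, at percentile 100 of matched random lists. Ccng1 was higher at 1.43, Bax at 1.14 and Rps27l at 0.55.

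These crypt values depend on how cells were kept and named. Naming rules added after the clusters had been seen keep cluster 12, a cycling group with the leukocyte gene Ptprc in 87.2% of its cells, out of the class; named by marker score alone, the class had a p53 median of 0.29 and Mdm2 at 0.64. With no mitochondrial limit the class became 281 Tg and 199 FMTg shallow cells, with median depths of 1239 and 1597 UMIs, a p53 median of 0.43, Mdm2 at -0.19 (-0.57 to 0.21) and Cdkn1a at -0.91. At a 10% limit, with 6 and 19 cells, Cdkn1a was at 0.033 and the p53 median 0.82. Of the crypt values, 18 of 24 list medians and 17 of 22 named genes moved by over 1.5-fold with no limit, and 5 and 17 when named by marker score alone.

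Several p53 targets had high crypt ratios from few Tg UMIs. Phlda3 had 2 and 132 UMIs, at 3.88 (1.99 to 6.94), and Zmat3, an RNA-binding protein gene, 2 and 100, at 3.47 (1.58 to 6.54). Dcxr was at 3.37 (1.48 to 6.44) and Gdf15, a stress cytokine gene, at 3.06 (1.16 to 6.13). Outside the p53 list, Ly6a, a surface antigen gene, was at 4.37 (2.81 to 6.66), S100a6 at 3.43 and AC160336.1 at 3.44. Crip2 had 0 and 117 UMIs, 8.67-fold higher with Tg set to 3 counts, with a lower interval end of 2.795 in log2. The goblet markers Agr2, Spink4 and Tff3 were at 6.19 (3.70 to 11.50), 3.20 and 2.64, and the enteroendocrine marker Chga at 5.09 (2.59 to 10.40). Agr2 had UMIs in 10 FMTg cells and Chga in 4. Spink4 and Tff3 turned to -1.04 (-1.51 to -0.58) and -1.99 (-2.20 to -1.79) with no mitochondrial limit, while Agr2, at -0.55 (-1.35 to 0.28), and Chga, at -1.15 (-3.06 to 0.75), had intervals that included 0.

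Among the genes with the lowest crypt ratios, Smoc2, a stem cell gene, was at -1.28, Cnn3 at -1.91, the carbonic anhydrase gene Car4 at -1.44 and Arg2 at -1.37. Atad2 was at -1.34, Aldh1b1 at -1.31, Pmvk at -1.24, Idnk at -1.17 and the interferon regulator Irf1 at -1.17. Gm10260, at -1.16, is uncertain as a copy of another gene. With no mitochondrial limit Smoc2 was at -0.26, Aldh1b1 at -0.36, Gm10260 at -0.43, Atad2 at -0.47, Pmvk at -0.65, Car4 at -0.72 and Cnn3 at -0.90. Named by marker score alone, Smoc2 was at -0.34, Aldh1b1 at -0.38, Car4 at -0.52, Arg2 at -0.53, Pmvk at -0.56 and Cnn3 at -0.95, and at a 10% limit Car4 was at -2.33.

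S phase genes were lower in FMTg crypt-progenitor-like cells, with a median of -0.46 (-0.65 to -0.25) and 16 of 38 at least 1.5-fold lower. Among them Cdca7 was at -0.82, Pcna, the replication clamp gene, at -0.72, Gmnn at -0.66 and Nasp at -0.60. With no mitochondrial limit the median was 0.20. G2 and M phase genes had a median of 0.12 (-0.036 to 0.19), and -0.22 when named by marker score alone, with Nusap1 at 1.24. At 2000 UMIs per cell, 10 of 10 Tg cells (100%, exact interval 69.2 to 100) and 35 of 37 FMTg cells (94.6%, 81.8 to 99.3) had at least 3 UMIs of these lists, with 0 cells left out. Unthinned, the share was 100% in both libraries, and cycling markers helped to name the class.

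Stem cell genes had a median of -0.19 in the crypt class, with Cd44 and Sox9 higher at 2.34 and 1.25; the median was 0.56 with no limit. MHC class II genes were lower, with a median of -0.49 and 3 of 7 at least 1.5-fold lower, but 0.16 with no limit. Proximal intestine genes had a median of 0.70 and lipid absorption genes 0.50, with Apoa4 at 1.72 and Fabp1 at 1.55. The antimicrobial, brush border and antioxidant medians were 0.46, 0.48 and 0.46. At a 10% limit these 5 medians were -0.20, -0.33, -0.24, -0.49 and -0.14, and with no limit -1.14, -1.35, 0.21, -1.69 and -0.049. Interferon genes had a median of 0.64 (-0.054 to 1.14), and -1.04 with no limit. Haemoglobin had 0 measured genes in the crypt class.

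**Figure D2:**
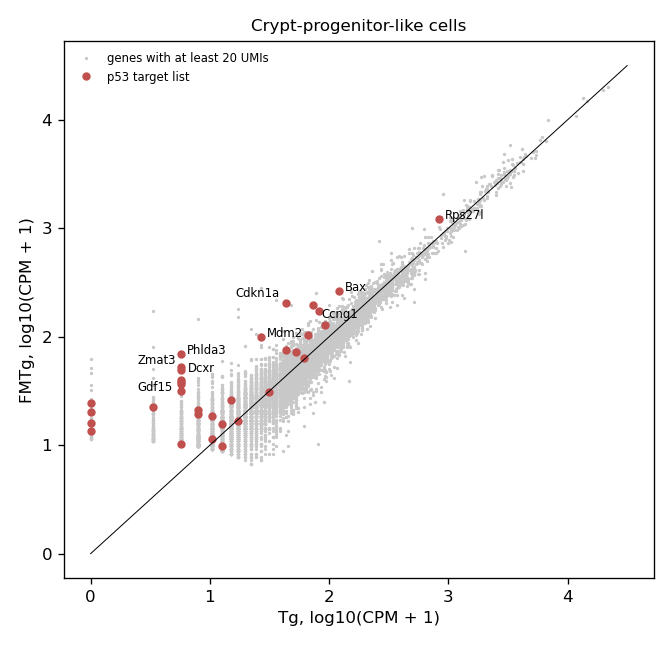
Expression per gene in crypt-progenitor-like cells, as log10(CPM + 1), Tg on the horizontal and FMTg on the vertical axis. Each point is 1 gene summed over 10 Tg or 37 FMTg cells; Cdkn1a, with 18 and 391 UMIs, lies on the FMTg side.

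Over all cells, which needs no cell naming, p53 targets were higher in FMTg as well. Mdm2 had 2721 UMIs in Tg (2620 to 2825) and 3453 in FMTg (3339 to 3570), a log2 ratio of 0.61 (0.54 to 0.68). Cdkn1a was at 0.55 (0.51 to 0.59). Trp53 was at 0.32 (0.20 to 0.44), but ran from 0.013 to 0.48 over 15 alternatives. Its ratios in enterocyte-like and crypt-progenitor-like cells, given above, were slightly negative. Whether the all-cell Trp53 value follows from the mix of cells was not tested. The 40 measured p53 targets had a median of 0.47 (0.46 to 0.57), with 16 at least 1.5-fold higher and 0 lower, at percentile 100 of matched random lists. Eda2r was at 2.30, Psrc1 at 1.72, Sesn2 at 1.25 and Phlda3 at 1.11.

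Cell cycle genes were higher over all cells, beside 10 Tg and 37 FMTg crypt-progenitor-like cells. G2 and M phase genes had a median of 0.88, with 38 of 52 at least 1.5-fold higher and the mitotic gene Cdc20 at 1.78, but 0.26 with equal weight per cell. S phase genes had 0.35 and stem cell genes 0.92, with Olfm4 at 1.69 and Cd44 at -1.78. Interferon genes had 0.28, but -0.60 at a 10% limit. Antimicrobial genes were lower at -1.27, with Ang4 at -3.62, though the median was -0.19 at a 10% limit. Goblet-like cells, with Ang4 among the leading genes of their cluster, were 4.15% of Tg and 1.64% of FMTg cells. The stress list was lower at -0.46, with Hspa1a at -3.24.

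Among the genes with the highest ratios over all cells, Zfp182, a zinc finger gene, had 0 and 393 UMIs, in 349 FMTg cells. With Tg set to 3 counts it was 157-fold higher, with a lower interval end of 6.99 in log2. Il22, an epithelial repair cytokine gene on chromosome 10 from 118204942 to 118210047, had 0 and 354 UMIs from 6 cells. It was 142-fold higher with Tg set to 3 counts, with a lower interval end of 6.84 in log2. Dynlt1b, with 1 and 169 UMIs, at 7.67 (5.17 to 12.98), has close copies and is uncertain. Klrb1a, a natural killer receptor gene, was at 4.87, Gm42047 at 4.28, the peptide transporter gene Slc15a2 at 3.41 and Bbs7 at 3.59. The tachykinin gene Tac1 was at 4.89, but at 0.77 (-0.49 to 2.14) at a 50% limit, and the keratin gene Krt15 at 3.59, but at -0.21 with equal weight per cell.

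Among the genes with the lowest ratios over all cells, Gm35082 had 560 and 6 UMIs (-6.28) in 467 Tg and 6 FMTg cells. The neutrophil-attracting chemokine gene Cxcl2 was at -3.78, from 2680 Tg and 162 FMTg UMIs. Neutrophil-like cells, 53 in Tg and 7 in FMTg, held 937 and 77 of them, and inside that class the ratio was -0.65. How much of the all-cell Cxcl2 value follows from the mix of cells was not tested. The hormone genes Sst and Iapp were at -8.06 and -4.32, but single cells decided both values. With doublets kept, Sst was at -0.71, with 3434 of 3457 FMTg UMIs in 1 cell and 3336 of 6765 Tg UMIs in another, and Iapp was at 0.23 (-0.040 to 0.49), with 224 of 234 FMTg UMIs in 1 cell. At a 10% limit they turned to 0.93 and 2.79. Gm5483 was at -7.16 (-12.47 to -4.66). With FMTg set to 3 counts, Asic5 was 29.7-fold lower, with an upper interval end of -4.57 in log2. It turned to 1.98 at a 10% limit, where its 67 FMTg UMIs lay in 1 cell. Ear1, from 2 Tg cells, was 28.3-fold lower with FMTg set to 3 counts, with an upper interval end of -4.50. The pancreatic genes Cela2a, Cela3b and 2210010C04Rik, at -3.88, -3.79 and -3.88, have close copies and are uncertain. They also rest on few Tg cells. For Cela2a 215 of 230 and for Cela3b 318 of 332 Tg UMIs came from 3 enterocyte-like cells each. The 106 Tg UMIs of 2210010C04Rik came from 10 cells. Of the genes ranked over all cells and Mdm2, Trp53 and Cdkn1a, counting those with UMIs in both libraries, 11 of 18 moved by over 1.5-fold at a 10% limit, 10 of 19 with no limit and 8 of 19 with equal weight per cell.

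The p53 list differed in size between the other cell classes. In T-like or NK-like cells the median was 0.43 (0.28 to 0.50), with Cdkn1a at 1.17 (0.95 to 1.40), Psrc1 at 2.17 and Phlda3 at 1.82, while Mdm2 was at 0.080 (-0.099 to 0.26). Clusters 1 and 2 of that class had medians of 0.49 and 0.65, and clusters 3, 7 and 8 had 0.054, -0.28 and -0.030. The epithelial gene Epcam had a UMI in 71% and 56.1% of cells of clusters 1 and 2, both libraries together. In clusters 3, 7 and 8 it had a UMI in 39.8%, 30.8% and 38.1% of cells. Whether background epithelial RNA adds to these p53 medians was not tested. In B-like cells the median was 0.12 (-0.050 to 0.29), with Mdm2 at -0.16 and Cdkn1a at -0.026. Cdkn1a was at 47.0 CPM in Tg and 46.1 in FMTg B-like cells, against 538 and 916 in enterocyte-like cells. B-like cells also held RNA of the enterocyte gene Fabp2, at 517 and 147 CPM. How much of the B-like p53 values is background RNA was not tested. In goblet-like cells, the mucus cells, it was -0.015 (-0.16 to 0.14), but 0.41 at a 50% mitochondrial limit, with Mdm2 at 0.60 and Cdkn1a at -0.080. In tuft-like cells, the chemosensory cells, it was 0.56 (0.37 to 0.71), with Mdm2 at 0.76 and Trp53inp1 at 1.23, beside the enterocyte genes Apoa4 at 0.81 and Reg3b at -0.54.

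Macrophage-like or dendritic-like cells had a p53 median of 0.58 (0.45 to 0.93), with Mdm2 at 0.54 and Cdkn1a at 1.003. Enteroendocrine-like cells, the hormone cells, 14 in Tg and 15 in FMTg, had 2.03 (1.82 to 2.53), with Mdm2 at 2.44 and Ccng1 at 3.16, but 0.95 at a 50% limit. Enterocyte genes were higher in the same cells, with Apoa1 at 2.79, Apoa4 at 3.14 and Reg3b at 2.30 and list medians of 1.15 for lipid absorption and 1.44 for brush border genes, at median depths of 7662 and 12917 UMIs. Plasma-like cells had 0.89 over 11 genes, with Mdm2 at 1.36, but -0.052 when genes needed 100 UMIs. Apoa1 and Apoa4 were higher there too, at 2.21 and 1.51, while Reg3b was at -1.08 and the lipid absorption median was -0.13, at median depths of 3234 and 12365 UMIs. Neutrophil-like cells had 3 measured targets, with a median of 0.96 (-0.55 to 1.72). The differences between classes were not tested. Another scaling moved the median of all genes by 0.11 in B-like (DESeq2), 0.14 in plasma-like (TMM) and -0.15 in enteroendocrine-like cells (total without mitochondrial and abundant genes) on the log2 scale.

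At the mitochondrial limit used, myeloid and goblet-like cells were a smaller share of FMTg than of Tg cells, and T-like or NK-like and B-like cells a larger one. Neutrophil-like cells were 53 of 2913 Tg cells, an exact binomial share of 1.82% (1.37 to 2.37), and 7 of 2675 FMTg cells, 0.262% (0.105 to 0.538). Macrophage-like or dendritic-like cells were 6.21% (5.36 to 7.15) of Tg and 1.53% (1.10 to 2.07) of FMTg cells. Goblet-like cells were 15.5% (13.0 to 18.2) of Tg and 6.53% (4.78 to 8.67) of FMTg epithelial cells, and tuft-like cells 6.51% (4.89 to 8.48) and 9.20% (7.13 to 11.6). Crypt-progenitor-like cells were 1.28% (0.614 to 2.34) of Tg and 5.49% (3.89 to 7.49) of FMTg epithelial cells. That difference of 4.21 percentage points (2.30 to 6.32) turned to -3.20 with no mitochondrial limit and was 24.0 at 10%.

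Enterocyte-like cells were 73.9% and 75.4% of epithelial cells. T-like or NK-like cells were 44.1% and 48.5% of all cells, and B-like cells 16.4% and 20.1%, differences of 4.34 percentage points (1.70 to 6.98) and 3.67 percentage points (1.62 to 5.73). At a 50% limit these were -2.88 (-4.81 to -0.958) and 0.874 (-0.592 to 2.33) points. Immune cells together differed by 2.21 percentage points (-0.214 to 4.62), which was -8.15 at a 50% limit. Paneth-like cells of cluster 22, 8 in each library, had Ptprc in 81.2% of cells. Clusters 12 and 18, left unnamed, held 3.78% of Tg and 3.25% of FMTg cells. The mitochondrial limit, dissociation and capture can set all of these shares.

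**Figure D3:**
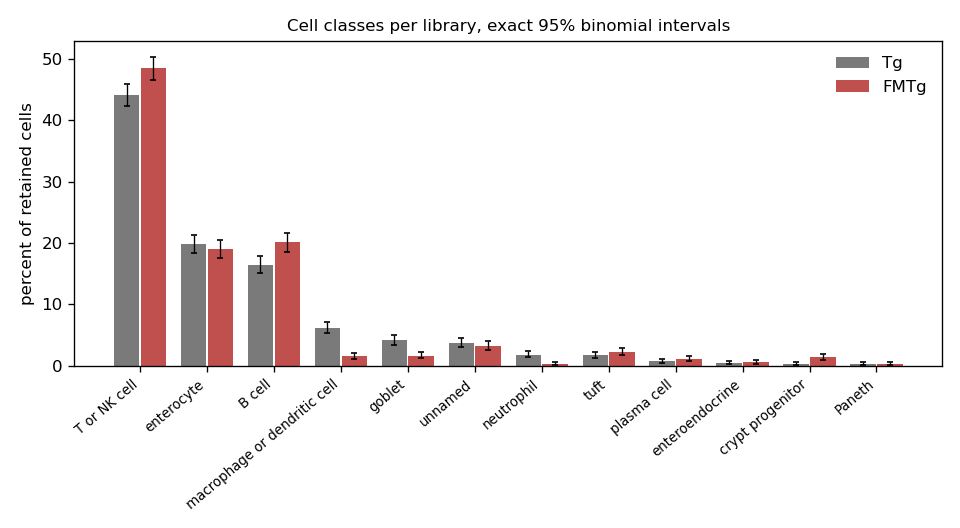
Share of retained cells in each class per library, in percent. Bars start at 0 and lines are exact 95% binomial intervals, which cover counting error only; neutrophil-like cells were 1.82% of Tg and 0.262% of FMTg cells.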

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

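The tests of the p53 pattern in this part were chosen only after the result was seen.

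Barcodes that the mitochondrial limit removed, 2946 in Tg and 3353 in FMTg, also carried more p53 target RNA in FMTg, outside the cells used in the report. The p53 list median in them was 0.48 (0.41 to 0.54), with 17 of 39 measured targets at least 1.5-fold higher and 0 lower, while matched random lists had a median of 0.18.

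In enterocyte-like cells the p53 list median was 0.64 (0.54 to 0.70). If different clusters in the libraries were the source, the median inside a cluster would lie near 0. But in 2 of the 3 clusters compared, 4 and 9, it was 0.60 (0.46 to 0.66) and 0.72 (0.55 to 0.82). In cluster 6 it was 0.31 (0.011 to 0.70) over 12 measured genes, which leaves this open there. Clusters 5, with 22 Tg and 239 FMTg cells, and 13, with 87 and 28, had too few cells to be compared. For them this stays open as well. Random lists matched on expression had a median of 0.060, so genes of like expression were not shifted as the p53 list was. This restates the percentile among random lists given above, and scaling to the class total already removes a shift of all genes. It is therefore not separate support. A candidate explanation is p53 activity after loss of Mdm2, which the group labels name, which Mdm2 UMIs do not show and which remains a hypothesis. Any other difference between the mice or in how the 2 libraries were made stays open, since each group has 1 library.

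The following lists were higher in 1 cell class and lower in another, and the difference between the classes was not tested. The interferon response median was 1.01 (0.89 to 1.12) in enterocyte-like and -0.31 (-0.50 to -0.11) in B-like cells, but the former was -0.88 in cluster 6 and -0.34 at a 10% mitochondrial limit. The stress list median was 0.14 (0.027 to 0.20) in enterocyte-like and -0.63 (-0.72 to -0.48) in T-like or NK-like cells. The enterocyte-like stress value was -0.24 without cluster 5, which is mostly of FMTg, -0.77 at a 10% mitochondrial limit and 0.038, -0.32 and -0.69 in clusters 4, 6 and 9. Antimicrobial genes had 0.46 (0.35 to 0.51) in crypt-progenitor-like and -1.53 (-1.60 to -0.93) in B-like cells, brush border genes 0.48 (0.013 to 0.64) and -0.74 (-0.96 to -0.52), and proximal intestine genes 0.70 (0.42 to 1.03) and -0.65 (-1.07 to -0.17). At a 10% mitochondrial limit the crypt medians were -0.24, -0.49 and -0.20. The B-like values of these epithelial lists are read as background RNA, not as expression: in T-like or NK-like cells the medians were -1.14, -0.61 and -0.44, and Reg3b had a UMI in 99.6% of Tg and 91.1% of FMTg B-like cells, against 99.2% and 93.8% of T-like or NK-like cells, at median depths of 3354 and 3206 UMIs in the former. Haemoglobin genes had 5.94 (5.28 to 6.63) in B-like and -0.34 (-0.54 to -0.15) in T-like or NK-like cells. Fabp1, an enterocyte gene, had a UMI in 76.3% of Tg and 46.8% of FMTg T-like or NK-like cells, at median depths of 4834 and 4558 UMIs.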

How the results depend on the processing

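The 50% mitochondrial limit, the scrublet automatic threshold, naming by marker score alone and the enterocyte-like class without either of its 2 doubted clusters were chosen after seeing the data. Over 19 main results and 22 alternatives, 255 values stayed within the counting interval, 39 moved beyond it and 3 turned direction. For the other 137 results, 1736 values stayed, 393 moved and 47 turned. Only ratios at least 1.5-fold from 1, or shares whose interval leaves out 0, count as turned: of the rest, 4 main and 70 other values that moved, and 17 and 53 that stayed, had the other sign. The p53 list median ran from 0.46 to 0.84 in enterocyte-like cells, from 0.36 to 0.49 in all cells, from 0.29 to 1.28 in crypt-progenitor-like, 0.41 to 0.61 in tuft-like, 0.48 to 0.88 in macrophage-like or dendritic-like, 0.30 to 0.53 in T-like or NK-like and 0.0054 to 0.24 in B-like cells. Values below are log2 ratios or, for shares, FMTg minus Tg in percentage points, and the cause was not tested except for Gm35082. Its value at a 10% limit rests on 4 and 0 UMIs, with the library at 0 set to 3 counts, so that floor sets its sign. Trp53 there rests on 4 and 3 UMIs, at 2.17 (-0.60 to 4.74). The pancreatic genes with no limit rest on 3 to 30 UMIs per library, and their intervals include 0. At a 10% mitochondrial limit, the p53 list was at 0.82, the proximal list at -0.20 and Tff3 at -2.03 in crypt-progenitor-like cells. In enterocyte-like cells the p53 list was at 0.84, the interferon list at -0.34, Mdm2 at 1.31, Trp53 at 2.17 and Gm35082 at 2.17. In all cells the p53 list was at 0.39, the haemoglobin list at -4.83, Mdm2 at 0.34, Trp53 at 0.48, Sst at 0.93, Asic5 at 1.98 and Iapp at 2.79. In enteroendocrine-like cells the p53 list was at 1.61. Under it, the crypt share differed by 24.0 points. With no mitochondrial limit, the p53 list was at 0.43, the interferon list at -1.04, the proximal list at -1.14, Mdm2 at -0.19, Cdkn1a at -0.91, Agr2 at -0.55, Chga at -1.15, Spink4 at -1.04 and Tff3 at -1.99 in crypt-progenitor-like cells. In enterocyte-like cells the p53 list was at 0.46, Mdm2 at 0.70, Try5 at 0.42, Cela3b at 2.002, Cela2a at 1.15, Prss2 at 0.42, Ctrb1 at 0.42 and Try4 at 0.25. In all cells the p53 list was at 0.42, Trp53 at 0.16 and Iapp at 0.022. In enteroendocrine-like cells the p53 list was at 0.98. Under it, the crypt share differed by -3.20 points. With at least 1000 UMIs per cell, Iapp was at 0.22 in all cells. In enteroendocrine-like cells the p53 list was at 1.79. With doublets kept, Prss2 was at 0.41, Ctrb1 at 0.83 and Try4 at 0.90 in enterocyte-like cells. In all cells Iapp was at 0.23. With TMM scaling, Mdm2 was at 0.83 in enterocyte-like cells. In all cells the p53 list was at 0.41. In T-like or NK-like cells the p53 list was at 0.53. With DESeq2 size factors, the p53 list was at 0.39 and Mdm2 at 0.53 in all cells. In T-like or NK-like cells the p53 list was at 0.51. Scaled to totals without mitochondrial and abundant genes, the p53 list was at 0.44 in all cells. With at least 100 UMIs per gene, the Wnt list was at -0.083 in enterocyte-like cells. In plasma-like cells the p53 list was at -0.052. In enteroendocrine-like cells the p53 list was at 1.70. With at least 1 UMI per gene, the p53 list was at 1.74 in enteroendocrine-like cells. With the mean of CPM per cell, Trp53 was at 0.62 in enterocyte-like cells. In all cells the p53 list was at 0.36, Mdm2 at 0.30 and Krt15 at -0.21. In plasma-like cells the p53 list was at 1.503. At resolution 0.5, Ctrb1 was at 1.40 and Try4 at 0.88 in enterocyte-like cells. With each library clustered on its own, Prss2 was at 1.36, Ctrb1 at 1.36 and Try4 at 0.85 in enterocyte-like cells. With all variable genes, Prss2 was at 0.40, Ctrb1 at 0.99 and Try4 at 0.89 in enterocyte-like cells.

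Of the alternatives chosen after seeing the data, these gave other values. At a 50% mitochondrial limit, Cela3b was at 2.76, Cela2a at 1.24, Prss2 at 1.63 and Ctrb1 at 0.79 in enterocyte-like cells. In all cells the p53 list was at 0.42, Mdm2 at 0.76 and Trp53 at 0.013. In goblet-like cells the p53 list was at 0.41. In enteroendocrine-like cells the p53 list was at 0.95. Under it, the crypt share differed by 1.12 points and the immune share by -8.15 points. With the scrublet automatic threshold, Prss2 was at 0.41, Ctrb1 at 0.996 and Try4 at 0.90 in enterocyte-like cells. In all cells Iapp was at 0.23. Named by marker score alone, the p53 list was at 0.29 and Mdm2 at 0.64 in crypt-progenitor-like cells. Without the cluster mostly of FMTg, Mdm2 was at 0.68 in enterocyte-like cells. Without the shallow cluster, Ctrb1 was at 1.40 and Try4 at 0.88 in enterocyte-like cells. Clustering each library on its own gave no crypt p53, Mdm2, Trp53 or cycling value, and a 10% mitochondrial limit gave no p53 value for macrophage-like or dendritic-like cells. The crypt values rest on 10 Tg cells, which limits their precision. No paired analysis was possible because each group has 1 library.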

Other observations

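The bound for passenger DNA and the tests of immune yield and of the mitochondrial limit in this part were chosen only after the result was seen. An earlier bound for passenger DNA, on the exact interval of the share of genes on the chromosome of Mdm2, was not met, since with 4 genes the interval reaches 60.2%; it was replaced because the position of a gene carries no sampling error.

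In macrophage-like or dendritic-like cells MHC class II genes, which present antigen, had a median of 2.11 (1.89 to 2.28), with 7 of 7 at least 1.5-fold higher in FMTg. Cd74 was at 1.96 (1.84 to 2.07), H2-Aa at 2.33 and H2-Eb1 at 2.46, while Cxcl2 was lower at -1.93 and the cytokine gene Il1b at -1.94. The MHC class II median was -0.16 (-0.29 to -0.10) in B-like and -0.039 (-0.31 to 0.20) in T-like or NK-like cells, and 0 of its genes were measured in neutrophil-like cells. Cluster 10, with Ccl9, Fn1 and Ccl2 as leading genes, held 161 Tg and 29 FMTg macrophage-like or dendritic-like cells. Cluster 20, with C1qa, Apoe and Lyz1, held 20 and 12. Cluster 10 was thus 89.0% of the class in Tg and 70.7% in FMTg. These lists were not computed inside either cluster, so a different mix of cells cannot be told apart from a difference within them. In T-like or NK-like cells the stress list had a median of -0.63, with Hspa1a at -5.93 (-7.81 to -4.55) from 255 and 4 UMIs, Hspa1b at 525 and 11 UMIs and Hsp90aa1 at -1.22. In B-like cells the stress median was -0.62, with 11 of 17 genes at least 1.5-fold lower.

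Epithelial classes differed as well. In tuft-like cells the interferon median was 0.87 (0.59 to 1.10), with 14 of 22 genes at least 1.5-fold higher, Ifit1 at 2.97 (2.07 to 4.01) and Rsad2 at 3.37 (2.07 to 5.04). In goblet-like cells antimicrobial genes had a median of -0.54 (-0.72 to -0.44), with Reg1 at -2.80 and Lyz1 at -3.50, beside the enterocyte genes Fabp2 at -1.31 and Apoa4 at 1.95. Unfolded protein genes had -0.37 there, with the chaperone gene Hspa5 at -0.77. These values in single classes were not recomputed under the alternatives.

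Across 5 cell classes, 4 genes were at least 4-fold apart, beyond counting error, in 3 or more. Zfp182 on chromosome X and Gm42047 on chromosome 8 were higher in FMTg, and Gm35082 on chromosome 7 and Hspa1b on chromosome 17 were lower. DNA around the targeted Mdm2 locus could carry such differences. Of these 4 genes, 0% lie on the chromosome of Mdm2, which argues against that for them. Other DNA differences between the mice, and differences in how the libraries were made, stay open. Hspa1b is also on the immediate early and dissociation stress list, whose median was -0.63 in T-like or NK-like and -0.62 in B-like cells. Il22, which lies near Mdm2 on chromosome 10 from 118204942 to 118210047, had UMIs in 6 FMTg cells and was not among these genes. Dynlt1b, with 1 and 169 UMIs, might lose Tg UMIs to its copies. Such a move alone would leave the family sum equal in both libraries. That sum was higher in FMTg, with a log2 ratio of 0.63 (0.49 to 0.77). Dynlt1a was also higher in FMTg, with 64 and 261 UMIs. Dynlt1c and Dynlt1f had more UMIs in Tg before scaling, the latter 550 and 407. These values argue against a move within the family as the whole source for Dynlt1b. The interval of the sum spans the 1.5-fold bound of that test, so a partial move cannot be told apart.

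Neutrophil-like and macrophage-like or dendritic-like cells were fewer in FMTg. Filters and clustering could set this, but over all barcodes 125 of 6270 Tg and 18 of 6382 FMTg barcodes had UMIs of at least 3 neutrophil markers, a share 7.07-fold higher in Tg. Those markers include Cxcl2 and Il1b, which macrophage-like or dendritic-like cells also carried, at a lower level in FMTg. The count is therefore not of neutrophils alone. A count of macrophage or dendritic markers cannot single out such cells, since 52.8% of Tg and 56.2% of FMTg barcodes had at least 3. Clustering therefore stays open for macrophage-like or dendritic-like cells. With no mitochondrial limit their share still differed by -2.99 (-3.67 to -2.33) percentage points. A lower yield of all immune cells would lower their share of all cells as well, but it was 69.3% in Tg and 71.6% in FMTg, and of 3 limits compared the lowest FMTg to Tg ratio of that share, at 50%, was 0.856 (0.809 to 0.904), against 0.247 and 0.144 for the macrophage-like or dendritic-like and neutrophil-like shares at the limit used. The T-like or NK-like share differed by 1.78 (0.163 to 3.39) points with no limit and -2.88 (-4.81 to -0.958) at a 50% limit, against 4.34 at the limit used, and sampling, dissociation and the genotype stay open for the myeloid cells.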
